A study of Mus musculus with 7 samples.

How the data were processed

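RNA sequencing counts were analysed for 7 explant libraries, 4 wild type and 3 Lmnb1-/-. Per the labels, RNA was extracted from mouse epicardial explants with a PicoPure kit and the libraries were made with the Illumina TruSeq RNA v2 kit. The submitters' processing notes name TopHat, edgeR and the mm9 genome build, without versions or settings. The annotation and the counting program were not given in the sources used here.

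Each library had a deposited table with 22738 gene rows, a gene name and 2 unnamed columns of whole-number counts, and no normalization is recorded per the file headers. The first count column was used throughout. The second column held 16.6 to 19.6% of both columns' counts. It was high for genes with near-identical copies elsewhere in the genome, such as Gapdh, which had 0 to 10 counts in the first column and 46 to 133 in the second. It was therefore read as counts of reads that match several places, which is an inference from the values. Genes with close copies are underestimated in the first column and their levels are uncertain. Rows that repeat a gene name numbered 949 and held 0.0831% of the counts. They were kept apart. 13 rows carried a date in place of a gene name and are called as listed. The library kit named in the labels is not strand specific, so reads of overlapping genes on opposite strands cannot be told apart.

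Total counts per library ran from 1024898 to 3066936. Genes were filtered with filterByExpr, which left 10775, and scaled by TMM. The comparison used edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust dispersion and no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 fold changes are Lmnb1-/- over wild type, and their standard error was taken as the size of the fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to TMM-adjusted library totals, given as mean ± SD. The labels number the replicates but do not say whether they came from separate embryos or litters. Wild type libraries of both sexes were found, so at least some came from different embryos. The p-values weigh the group difference against the spread between these libraries, whatever their origin.

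Before the data were examined, 31 gene lists were fixed, and 28 with at least 5 tested members, other than sex-linked and reference genes, were tested with camera at a preset correlation of 0.01. The lists were tested again with an estimated correlation, with fry, and with an exact two-sided permutation test of a score per library over the 35 ways to divide the libraries into 4 and 3. The smallest p this design allows is 0.0286. The score was the mean of each member's centred log2 CPM with a prior count of 2. Of 732 list entries, 726 matched a gene row by symbol or synonym.

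Genes named in the text followed a rule fixed before the data were examined. It takes Lmnb1, Lmnb2 and Lmna. It takes the 12 largest increases and the 12 largest decreases among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and ranges of CPM that did not overlap. It also takes up to 4 members of smallest p in each list described, or up to 2 where no member passed. Genes named outside this rule are said to have been chosen after their values were seen.

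Alternatives fixed beforehand were RLE size factors, library totals without scaling, no count filter, a minimum CPM of 1 in 3 libraries, DESeq2 1.42.0, limma voom with and without sample weights, edgeR's exact test, a fold minimum of 1.2, a replicate block, removal of Y-linked genes and Xist, and leaving out each library in turn. Alternatives chosen after seeing the data were sex as a covariate, male libraries only, the sum of both count columns, removal of Rmrp and Rpph1, the nuclear envelope list without Lmnb1, the permutation test of list scores, and a block for groups of libraries with neighbouring numbers. The last used the library number that each table carries. A new group began wherever the gap was over 2, which placed wild type replicate 1 with Lmnb1-/- replicate 1, wild type replicates 2 and 3 together, and wild type replicate 4 with Lmnb1-/- replicates 2 and 3. The labels give no batch.

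The procedure was tested on simulated counts with the real libraries' means and sizes and 200 changed genes. After the filter 10619 genes were tested, among them 49, 48, 46 and 49 of the genes changed 1.5-fold, 2-fold, 3-fold and 4-fold. It recovered 22.4% of genes changed 1.5-fold, 66.7% of those changed 2-fold, 95.7% at 3-fold and 91.8% at 4-fold, and 4 of 136 calls were false. Genes were simulated independently, without variation shared between genes, so these rates need not hold for the real libraries. Gene order and chromosome came from a GRCm38 annotation, which placed 99.2% of the tested genes. Because the processing notes name mm9, no coordinates are printed. Replicates were compared in pairs within each group by chi-square over genes. The values per degree of freedom ran from 2.22 to 7.71, so no pair differed by sampling noise alone.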

Results

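Gene expression was measured by RNA sequencing in epicardial explants from E12.5 mouse embryo hearts. The epicardium is the outer cell layer of the heart, and its cells migrate out when ventricles are laid on gelatin. Hearts were removed after 48 hours and the remaining cells grew for a further 72 hours. There were 4 wild type libraries and 3 from embryos lacking Lmnb1, which encodes the nuclear lamina protein lamin B1, on a mixed C57BL/6 and 129 background. The series addresses the part lamin B1 plays in the timing of epicardial cell migration. Total counts were 2263377, 1024898, 2732236 and 2392374 in wild type replicates 1 to 4, and 3066936, 1786519 and 1891977 in Lmnb1-/- replicates 1 to 3. Xist and the Y-linked genes showed that wild type replicates 1 and 3 were female (Xist counts of 595 and 642), whereas wild type replicates 2 and 4 and all 3 Lmnb1-/- libraries were male.

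Lmnb1 was almost absent from the Lmnb1-/- explants. Its level was 204 ± 24.6 CPM in wild type (SD, n = 4) and 1.49 ± 0.498 CPM in Lmnb1-/- explants (SD, n = 3). The raw counts were 463, 185, 488 and 567 against 4, 2 and 4. This was a log2 fold change of -7.07 (SE 0.22) with an adjusted p of 3.67e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Pooled counts left 0.712% of the wild type level, with an exact 95% interval of 0.341 to 1.31% that covers counting error only. The other lamins showed no detectable difference by the same edgeR test. Lmnb2, encoding lamin B2, had a log2 fold change of 0.24 (SE 0.20, adjusted p = 0.634), and Lmna, encoding lamins A and C, had -0.03 (SE 0.11, adjusted p = 0.935).

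Loss of Lmnb1 was accompanied by a change in 76 of 10775 tested genes, 39 higher and 37 lower. Among the largest increases, Pgf, encoding placental growth factor, rose 4.36-fold from 7.12 ± 3.13 to 30.2 ± 7.77 CPM. Tfpi2, a protease inhibitor, rose 3.48-fold from 4.76 ± 1.04 to 16.5 ± 7.14 CPM. The retinoic acid binding protein gene Crabp1 rose 3.33-fold from 5.38 ± 2.41 to 16.6 ± 6.03 CPM. These wild type levels are low, as 3 counts made 2.93 CPM of the total of wild type replicate 2. Rassf1, a Ras association domain gene described as a tumour suppressor, rose 3.36-fold from 80.2 ± 14.3 to 271 ± 38.0 CPM and Ptx3, encoding the secreted pentraxin 3, from 44.4 ± 10.6 to 127 ± 10.3 CPM. Among the genes that fell, Actg2, encoding smooth muscle gamma actin, went from 107 ± 39.8 to 23.4 ± 7.10 CPM, and Cspg4, encoding the pericyte proteoglycan NG2, from 153 ± 23.0 to 64.7 ± 15.2 CPM.

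The other genes with the largest increases were Slco4a1, Nog, which encodes the BMP antagonist noggin, Serpinb9b, Crip2, Abcb1b, Ptbp2 and Emp1. Emp1 was the most abundant of these, at 855 ± 115 CPM in wild type and 1529 ± 160 CPM in Lmnb1-/- explants. Their log2 fold changes ran from 0.84 for Emp1 to 1.70 for Slco4a1. The other large decreases were in the gene listed as 5-Sep, a date in place of a symbol, and in Pde1a, Speg, Dusp27, Adamts2, Sema5a, H1f0, Nacc2 and Sync. Speg encodes a striated muscle kinase, Sync an intermediate filament partner in muscle, and H1f0 a linker histone. Their log2 fold changes ran from -1.10 for Sync to -1.49 for 5-Sep. Adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 5.58e-05 for Rassf1, 0.00112 for Ptx3, 0.00819 for Cspg4, 0.0130 for Emp1, 0.0193 for Pgf and 0.0491 for Actg2.

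**Figure D1:**
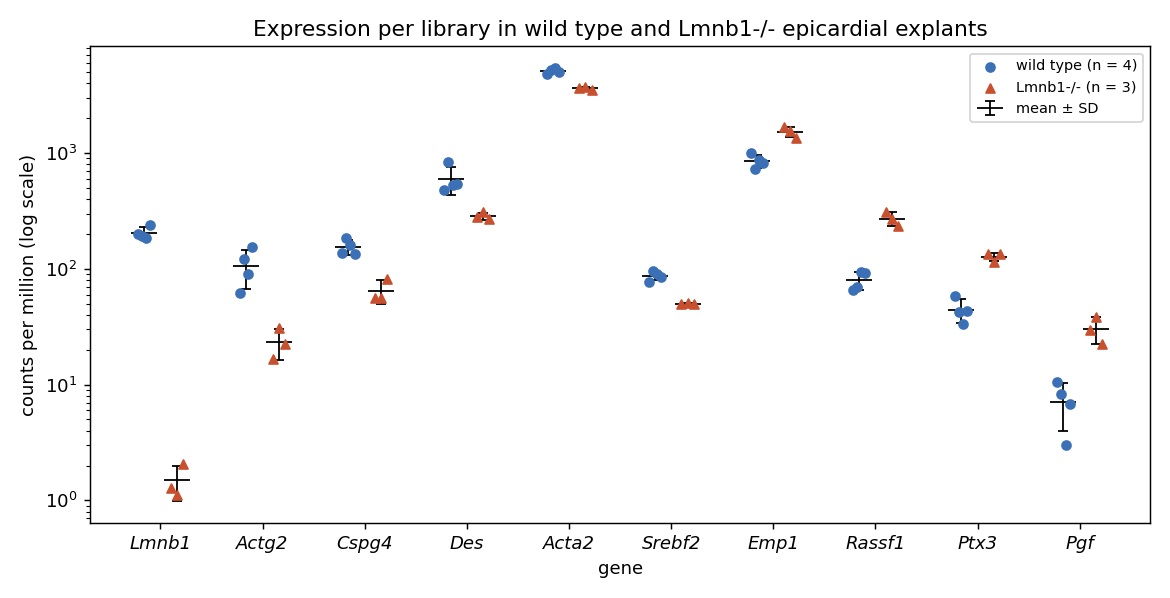
CPM on a log axis for 10 genes in each wild type library (circles, n = 4) and each Lmnb1-/- library (triangles, n = 3), with bars for mean ± SD. Lmnb1 stood at 204 ± 24.6 CPM in wild type and 1.49 ± 0.498 CPM in Lmnb1-/- libraries, and the groups did not overlap for any gene drawn.

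Among the 76 genes, 25 changed by more than 2-fold, 10 of them higher and 15 lower. CPM ranges of the groups did not overlap in any of the 76. These genes were selected by a test on the same libraries, which favours ranges that lie apart, so this is no separate support. Among all tested genes 13.3% had ranges that did not overlap, where chance gives 5.71% on average. Genes that vary together can move this share in a single division of the libraries. It was not computed for other divisions, so the excess was not tested. With library totals in place of TMM, 73 genes passed, 47 higher and 26 lower. Within male libraries, 95 genes passed in edgeR's quasi-likelihood test, 29 higher and 66 lower, and 39 of the 76 were among them. All Lmnb1-/- libraries were male, so fold changes with sex as a covariate rest on the same wild type libraries, replicates 2 and 4. With sex as a covariate 38 passed, 11 higher and 27 lower, and 24 of the 76 were among them. Pgf, Tfpi2, Crabp1 and Nog lost their calls there (adjusted p = 0.0868, 0.128, 0.150 and 0.102), though their log2 fold changes stayed at 2.04, 1.82, 1.81 and 1.35, and Pgf passed within male libraries (0.0188). Of the other genes named above, Slco4a1, Crip2, Ptbp2, Pde1a, Dusp27, Adamts2, Sema5a, H1f0 and Sync also lost their calls with sex as a covariate (adjusted p = 0.0833, 0.0739, 0.0706, 0.0865, 0.136, 0.0706, 0.115, 0.0782 and 0.0846), and all kept their direction. Of these, Crip2, Ptbp2 and Adamts2 passed within male libraries (adjusted p = 0.0488, 0.0246 and 0.0373) and the others did not. With groups of libraries of neighbouring numbers as a block, 93 passed, 40 higher and 53 lower, 48 of them shared. Of these groups, that of wild type replicates 2 and 3 held no Lmnb1-/- library. The number of calls depended on single libraries. It was 279 without wild type replicate 1, 40 without wild type replicate 2, 28 without wild type replicate 4 and 13 without Lmnb1-/- replicate 3. It was 4 without wild type replicate 3 (Lmnb1, Rassf1, Ptx3 and Serpinb9b), 4 without Lmnb1-/- replicate 1 (Lmnb1, Rassf1, Ptx3 and Mrc1) and 3 without Lmnb1-/- replicate 2 (Lmnb1, Rassf1 and Ptx3). Mrc1, a macrophage gene, was named after its values were seen.

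Smooth muscle and pericyte genes were lower as a group in Lmnb1-/- explants. All 21 tested members had negative log2 fold changes, with a median of -0.82, and 5 of the 21 fell, Actg2, Cspg4, Des, Pdgfrb and Acta2. Des, encoding the intermediate filament desmin, went from 599 ± 162 to 286 ± 20.2 CPM and Pdgfrb, encoding the platelet-derived growth factor receptor of mural cells, from 65.8 ± 10.3 to 34.9 ± 1.96 CPM. The abundant Acta2, encoding smooth muscle alpha actin, fell from 5138 ± 249 to 3617 ± 108 CPM. Adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.0294 for Des, 0.0285 for Pdgfrb and 0.0367 for Acta2. Both female libraries were wild type, and the calls of Pdgfrb and Acta2 were lost with sex as a covariate (adjusted p = 0.0865 and 0.0938) and within male libraries (0.0522 and 0.0547). Their log2 fold changes hardly moved, from -0.90 and -0.51 to -0.89 and -0.51 in both settings. Both settings compare wild type replicates 2 and 4 with the Lmnb1-/- libraries, so they are not separate checks. The lost calls are by themselves no sign of an effect of sex. In all 12 members fell when adjusted over the list alone. The list passed camera with a Benjamini-Hochberg adjusted p of 1.39e-16, and the call was lost at adjusted p = 0.316 with an estimated correlation.

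The list's median was -0.89 within male libraries and -0.65 with the number groups as a block. The mean list score differed by -0.37 between wild type replicate 1 and Lmnb1-/- replicate 1, and by -0.88 between wild type replicate 4 and Lmnb1-/- replicates 2 and 3. No member passed without wild type replicate 3, Lmnb1-/- replicate 1 or Lmnb1-/- replicate 2. There were 9 passing members without wild type replicate 1, 3 without wild type replicate 2 (Cspg4, Des and Pdgfrb) and 1 without Lmnb1-/- replicate 3 (Cspg4). The count adjusted over the list alone was 17 without wild type replicate 1 and 6 to 8 without any other library. It was 18 within male libraries, 15 with sex as a covariate and 12 with the number groups as a block.

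Genes of cholesterol synthesis were also lower together. All 19 tested members were below 0, with a median log2 fold change of -0.52, and 1 of the 19, Srebf2, fell. Srebf2 encodes the transcription factor that drives this pathway and went from 87.5 ± 7.95 to 49.9 ± 1.03 CPM, with an adjusted p of 0.0193 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The members Fdft1 and Sqle had log2 fold changes of -0.81 and -0.61 and adjusted p-values of 0.0687 and 0.0835 in the same edgeR test. There were 15 members that fell adjusted over the list alone. Camera gave the list a Benjamini-Hochberg adjusted p of 1.77e-13, lost at adjusted p = 0.316 with an estimated correlation. The median was -0.49 within male libraries, where 3 members passed adjusted over the list alone (1 with sex as a covariate), and -0.46 with the number groups as a block, where 7 did. Srebf2 did not pass without wild type replicate 3 or without any of Lmnb1-/- replicates 1, 2 and 3.

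Extracellular matrix, adhesion and epicardial marker lists were called lower by camera at the preset correlation, with no single member past the threshold in that direction. Camera adjusted p-values were 7.85e-05 for fibroblast matrix, 1.61e-05 for basement membrane, 0.000300 for integrins and focal adhesion and 0.000561 for epicardial markers. All 4 calls were lost with an estimated correlation (adjusted p = 0.462, 0.568, 0.325 and 0.325). Fibroblast matrix genes had a median log2 fold change of -0.51, and 0 of 28 members passed, with Fbln2 at -0.58 and Col6a2 at -1.14, while 6 fell and 1 rose adjusted over the list alone. That count of lower members was 11 without wild type replicate 1, 3 without wild type replicate 4 or Lmnb1-/- replicate 2 and 0 without Lmnb1-/- replicate 1, and over all genes 8 fell and 1 rose without wild type replicate 1. Basement membrane genes had a median of -0.40, and 0 of 21 passed, with Agrn at -0.96 and Lamb2 at -0.64, while 6 fell and 1 rose adjusted over the list alone. Here 13 fell by that measure without wild type replicate 1, 3 without wild type replicate 4 or Lmnb1-/- replicate 2 and 0 without Lmnb1-/- replicate 1 or 3, and over all genes 6 fell without wild type replicate 1. In the integrin and focal adhesion list, with a median of -0.27, 1 of 27 members passed. This was Itga6, a laminin receptor subunit, which rose from 101 ± 24.7 to 178 ± 15.9 CPM (adjusted p = 0.0412 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Itga6 kept its call only on leaving out wild type replicate 1, among the 7 libraries left out in turn. It lost the call with sex as a covariate (adjusted p = 0.0739) and with the number groups as a block, but not within male libraries (0.0131). Itga5, Itgb8 and Itga1 had log2 fold changes of -0.47, -1.54 and -0.79 and did not pass. In this list 7 members fell and 1 rose adjusted over the list alone. The 7 became 10 without wild type replicate 1, 1 and 2 without wild type replicates 2 and 3, and 0 without wild type replicate 4 or any of Lmnb1-/- replicates 1, 2 and 3.

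Epicardial markers had a median log2 fold change of -0.33, with 16 of 20 members below 0 and 0 past the threshold over all genes, and 4 fell adjusted over the list alone. The 4 became 7 without wild type replicate 1, where 3 fell over all genes, 2 without Lmnb1-/- replicate 3 and 0 without Lmnb1-/- replicate 1. The transcription factor gene Bnc1 was at 301 ± 35.3 CPM in wild type and 214 ± 6.70 CPM in Lmnb1-/- explants, and the Wnt agonist gene Rspo1 at 36.2 ± 11.1 and 18.2 ± 4.12 CPM. The standard markers Wt1, Tbx18, Tcf21 and Aldh1a2, named after their values were seen, had log2 fold changes of -0.27, -0.37, -0.24 and -0.36, none of which passed. In the order of fibroblast matrix, basement membrane, integrin and epicardial lists, medians within male libraries were -0.53, -0.65, -0.34 and -0.36. With the number groups as a block they were -0.24, -0.33, -0.14 and -0.31. Over all genes, 3, 6, 1 and 1 members fell within male libraries, 2, 1, 2 and 2 with the block, and none with sex as a covariate. Adjusted over the list alone, 13, 14, 8 and 7 fell within male libraries and 11, 14, 3 and 5 with sex as a covariate. With the block 5, 6, 3 and 5 fell by that measure.

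DNA replication genes were higher as a group, though none passed singly. Of 30 tested members 29 were above 0, with a median log2 fold change of 0.42. Pcna, the replication clamp, was at 36.4 ± 8.08 CPM in wild type and 60.2 ± 5.88 CPM in Lmnb1-/- explants, and the cyclin gene Ccne2 at 46.3 ± 9.73 and 72.7 ± 6.72 CPM. There were 4 members that rose adjusted over the list alone. Camera gave a Benjamini-Hochberg adjusted p of 2.01e-10, lost at adjusted p = 0.462 with an estimated correlation. The score of wild type replicate 1, 0.30, lay among the Lmnb1-/- scores of 0.34, 0.24 and 0.16, and those of wild type replicates 2, 3 and 4 were -0.57, -0.31 and -0.16. Without wild type replicate 1, 9 members passed, and 20 did adjusted over the list alone. By that measure 0 passed without wild type replicate 3, Lmnb1-/- replicate 1 or Lmnb1-/- replicate 2. It gave 17 within male libraries, 7 with sex as a covariate and 1 with the number groups as a block. The median was 0.57 within male libraries and 0.19 with the number groups as a block.

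Targets of p53 were slightly higher, with 24 of 28 members above 0, a median log2 fold change of 0.22 and 0 past the threshold over all genes. Rps27l and Ei24 had log2 fold changes of 0.48 and 0.43. There were 9 that rose adjusted over the list alone, but 0 did with sex as a covariate or within male libraries, where the median was 0.12. That count was 5 without wild type replicate 1, 4 without wild type replicate 3 or 4, 2 without Lmnb1-/- replicate 1 or 3 and 0 without Lmnb1-/- replicate 2. Camera gave an adjusted p of 1.61e-05 and adjusted p = 0.325 with an estimated correlation. Mitosis genes had a median of 0.16, with 25 of 30 above 0, and genes of mitochondrial respiration 0.13, with 21 of 24 above 0. No member of either passed, including Ttk and Ndc80 at 0.33 and 0.35 and Cox5a and Cs at 0.32 and 0.24, nor did any adjusted over the list alone. Camera adjusted p-values were 0.00942 for both, and adjusted p = 0.654 and 0.634 with an estimated correlation. The mitosis call was lost without wild type replicate 2, wild type replicate 3 or Lmnb1-/- replicate 1 (camera adjusted p = 0.210, 0.201 and 0.114), and with the number groups as a block (0.978). The respiration call was lost without wild type replicate 2 or Lmnb1-/- replicate 2 (camera adjusted p = 0.0581 and 0.0819).

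**Figure D2:**
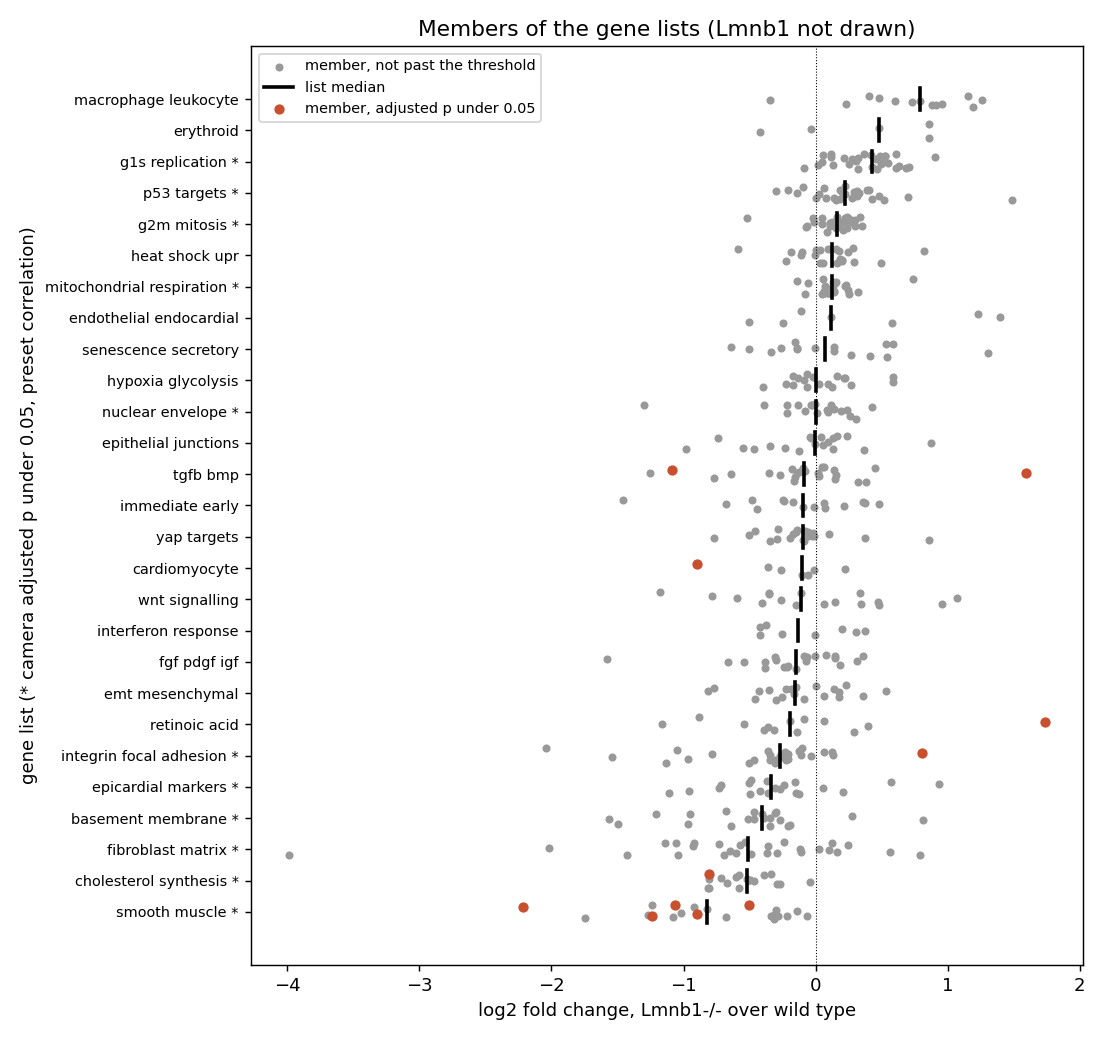
Log2 fold change of each tested member (points) of the tested gene lists, with the list median as a bar. Lmnb1 and 1 list were left out of the drawing. Members with an adjusted p under 0.05 in edgeR's quasi-likelihood test are orange. Smooth muscle (median -0.82) and cholesterol synthesis (median -0.52) had no member above 0.

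The nuclear envelope list was called lower because of Lmnb1 alone. Its camera adjusted p was 0.00942, with adjusted p = 0.316 using an estimated correlation and 0.653 without Lmnb1. Its mean log2 fold change was -0.38 and its median 0.0016. Apart from Lmnb1, no member of the 20 passed, with Tmpo, encoding a lamina-associated protein, at 0.42, Syne2 at -0.39 and the gene listed as Ppapdc3 at -1.30. Adjusted over the list alone, 2 members fell, Lmnb1 included, and 1 rose.

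Signalling lists held a few single changes and were not called as groups by camera in the main comparison. In the TGF-beta and BMP list, 1 of 24 members rose, Nog, from 6.25 ± 1.27 to 18.5 ± 0.894 CPM, and 1 fell, Tgfb3, from 544 ± 130 to 257 ± 18.5 CPM. Their adjusted p-values were 0.0193 and 0.0315 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tgfb2 and Pmepa1 had log2 fold changes of -0.77 and -0.64 and did not pass. Crabp1 was the only member of 13 to rise in the retinoic acid list. Adjusted over the list alone, 2 fell and 1 rose in the TGF-beta list, and 1 rose in the retinoic acid list. On leaving out each library in turn, Crabp1 passed only without wild type replicate 1 or 2, Tgfb3 without wild type replicate 1 or 4, and Nog without wild type replicate 1, 2 or 4.

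No camera call was made for these lists or for others, 17 of the 28 in all, with adjusted p-values from 0.121 to 0.901. Some were called under other settings. The TGF-beta and BMP list was called lower within male libraries (median -0.20, camera adjusted p = 0.000800), with sex as a covariate (0.0153) and without wild type replicate 1 (0.00427), and YAP targets were called lower with sex as a covariate (0.0441) and within male libraries (0.0479). Heat shock genes were called higher without wild type replicate 1 or 4 or Lmnb1-/- replicate 1 and with the replicate block, mesenchymal transition genes lower without wild type replicate 4, and growth factor signalling lower with no count filter. The epithelial junction list had a median of -0.0024, with Cdh3 at -0.55 and Ezr at -0.46, and the list of mesenchymal transition genes -0.16, with Zeb1 at -0.46 and Fn1 at -0.81. Medians were -0.10 for YAP targets, -0.11 for Wnt signalling, -0.15 for growth factor signalling, 0.07 for secretory senescence genes, -0.13 for interferon response, -0.10 for immediate early genes, 0.13 for heat shock and protein folding stress and 0.0037 for glycolysis. No member of these 10 lists passed over all genes. In those with any call adjusted over the list alone, 1 rose and 3 fell among epithelial junction genes, 1 rose and 2 fell among YAP targets, 1 rose among senescence genes, and 2 rose and 1 fell among immediate early genes.

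Markers of other cell types differed widely between explants. Summed macrophage markers were at 190, 96.6, 116 and 554 CPM in wild type replicates 1 to 4 and at 53.8, 378 and 946 CPM in Lmnb1-/- replicates 1 to 3. Their median log2 fold change of 0.79 had a camera adjusted p of 0.252, and none of 13 members passed, with C1qc at 1.26 and Emr1 at 1.16. Without Lmnb1-/- replicate 1 or wild type replicate 4 the list was called higher (medians of 1.45 and 1.70), as it was with the replicate block (median 1.41, camera adjusted p = 0.0459), and with the number groups as a block it was called lower (median -0.22, camera adjusted p = 0.0118). Without Lmnb1-/- replicate 3 the median was -0.36 (camera adjusted p = 0.462), so the higher median rested on that library. Red blood cell markers varied alike, from 25.4 CPM in Lmnb1-/- replicate 1 to 286 CPM in Lmnb1-/- replicate 3, with a list median of 0.48 and a camera adjusted p of 0.679, and were called higher without Lmnb1-/- replicate 1, while their median was -0.44 without Lmnb1-/- replicate 3. The Hba-a1 and Hba-a2 values were identical and are uncertain, since these genes are near-identical copies.

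Cardiomyocyte markers summed to 720 ± 157 CPM in wild type and 714 ± 107 CPM in Lmnb1-/- explants, and endothelial markers to 128 ± 22.6 and 144 ± 12.03 CPM. Their camera adjusted p-values were 0.252 and 0.283. In the cardiomyocyte list 1 of 7 tested members fell, the small heat shock protein gene Hspb7, from 31.5 ± 2.14 to 17.1 ± 2.58 CPM (adjusted p = 0.0466 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Hspb7 passed only without wild type replicate 1 among the libraries left out in turn, and neither with sex as a covariate nor within male libraries (adjusted p = 0.136 and 0.126). Nor did it pass with the number groups as a block. Kdr and Egfl7, the endothelial members of smallest p, had log2 fold changes of 1.40 and 0.57 and did not pass. Neural crest and glial markers summed to 30.1 ± 3.77 and 25.1 ± 8.52 CPM, and 1 member, Tubb3, was tested, at -0.23. None of 12 reference genes passed, and their median was 0.07.

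**Figure D3:**
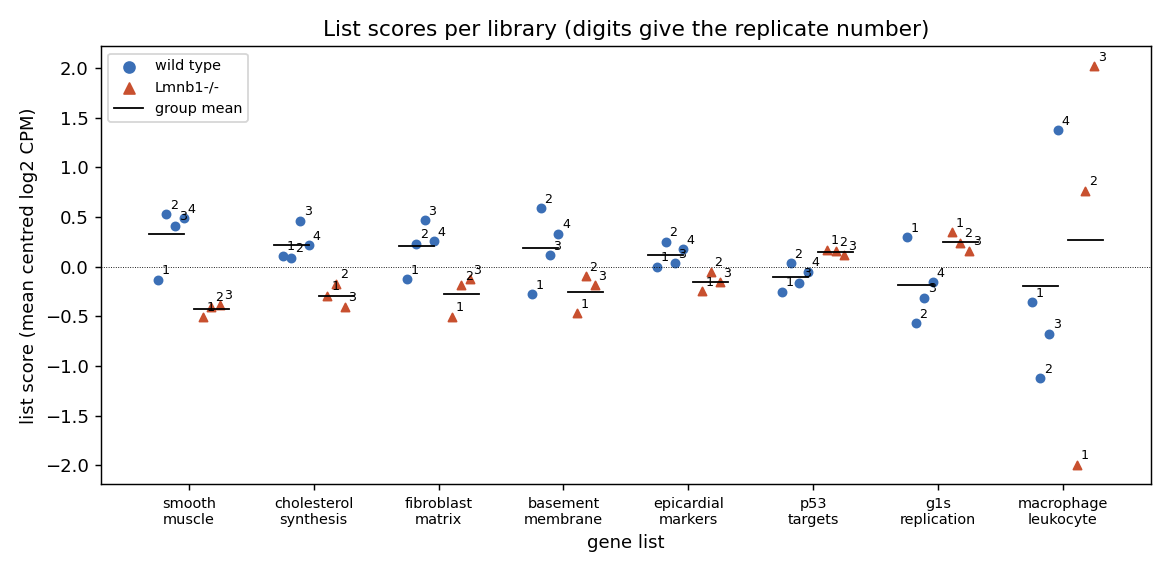
Score of 8 gene lists in each library, as the mean of centred log2 CPM over the members, for wild type (circles) and Lmnb1-/- (triangles), with group means as lines and replicate numbers beside the points. Wild type replicate 1 scored 0.30 for DNA replication, among the Lmnb1-/- libraries, and macrophage scores ran from -1.99 to 2.02 within the Lmnb1-/- group.

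Of the genes around Lmnb1 on chromosome 18, 34 tested genes lay within 5 Mb, and 1 of these changed, Pdgfrb. Elsewhere 73 of 10655 changed, which gave a two-sided p of 0.211 in Fisher's exact test. Within 10 Mb it was 1 of 64, with an exact p of 0.360.

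In total 11 of the 28 lists were called by camera at the preset correlation, 4 higher and 7 lower. The 7 include the nuclear envelope list, which was called because of Lmnb1 alone. With an estimated correlation 0 were called by camera, with 3 at an unadjusted p under 0.05, and by fry also 0, with 6 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0545. The exact permutation test of list scores gave 0 lists past the threshold after adjustment. With 28 lists and a smallest possible p of 0.0286, a list could pass only if many lists reached that p together. This 0 therefore cannot tell whether a list differed. In this test 2 lists had an unadjusted p of 0.0286, cholesterol and nuclear envelope. The nuclear envelope score includes Lmnb1, the targeted gene, and was not tested without it, so its p is no separate support.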

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

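In 127 comparisons of a named gene's level, a list score or the library total across the 4 wild type libraries, 6 had a library whose gap to the nearest other was large against the whole range, where chance gives about 6.35. Emr1, a macrophage gene, stood at 24.5 CPM in wild type replicate 4 against 7.23 to 8.26 CPM in the other wild type libraries. Igf2, a fetal growth factor gene, was at 556 CPM in wild type replicate 4 against 355 to 384 CPM. Zeb1 was at 102 CPM in wild type replicate 3 against 72.6 to 75.4 CPM, and Ifit2 at 50.5 CPM there against 38.2 to 39.6 CPM. Egr1, an immediate early gene, was at 35.1 CPM in wild type replicate 2 against 12.8 to 16.5 CPM. Sync was at 24.8 CPM in wild type replicate 1 against 34.1 to 35.4 CPM.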

How the results depend on the processing

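The sex, male-only, both-column, Rmrp and Rpph1, nuclear envelope, permutation and number group settings were chosen after seeing the data, and the cause of each shift below was not tested. All 76 genes kept their direction in all 23 alternatives for genes. Their CPM ranges did not overlap, so leaving out libraries could hardly reverse them, and the other settings refit the same counts. The kept direction is therefore no separate support. Lmnb1, Rassf1 and Ptx3 passed in all 23. Higher and lower counts, 39 and 37 in edgeR's quasi-likelihood test, became 83 and 97 with no count filter, 75 and 100 with DESeq2 (2301 genes without an adjusted p), 26 and 20 with limma voom, 65 and 67 with sample weights, 105 and 130 in edgeR's exact test, 3 and 4 with a fold minimum of 1.2, 11 and 27 with a sex covariate, 29 and 66 in male libraries, and 27 and 17 with both columns summed. List members that passed, 13, became 34 with no filter, 37 with DESeq2, 25 with sample weights, 47 in the exact test, 2 with the fold minimum, 6 with the sex covariate, 25 in male libraries, 7 with both columns and 25 with number groups as a block. On leaving out each library in turn, higher genes ranged from 2 (without Lmnb1-/- replicate 2) to 113 (without wild type replicate 1), lower genes from 1 to 166, passing members from 1 to 61, lists called higher from 2 (without wild type replicate 2) to 6 and lists called lower from 7 to 8. Lists called higher and lower, 4 and 7, were 0 and 0 with an estimated correlation, with fry and with the permutation test. The permutation test passes a list after adjustment only if many lists share its smallest p, so its counts of 0 decide nothing. Among lists called before or after the change, the direction of camera turned for the nuclear envelope list without Lmnb1 (median 0.012, adjusted p = 0.653), and with the number groups for mitosis (median 0.0066, adjusted p = 0.978) and macrophage genes (median -0.22, adjusted p = 0.0118). The uncalled macrophage median also turned, to -0.36 (adjusted p = 0.462), without Lmnb1-/- replicate 3.

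With the replicate number as a replicate block, 35 genes were higher and 42 lower, 35 of the 77 were shared with the 76, and 21 list members passed. Deviations from the group means correlated at 0.26, -0.16 and -0.09 between libraries of the same number, so the numbers do not pair the samples. Not every library correlated best with its own number.

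Small changes were often missed in simulated counts with independent genes, where 22.4% of 1.5-fold changes were recovered. Wild type replicate 2, with 1024898 counts, lay apart on the first principal component (31.8% of the variance).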

Other observations

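Other genes among the 76 were chosen for mention after their values were seen, and no shared theme was tested. Hbegf, encoding an epidermal growth factor receptor ligand, rose from 130 ± 11.2 to 196 ± 17.3 CPM, and Edn1, encoding endothelin 1, from 29.1 ± 3.46 to 50.8 ± 7.17 CPM. The stress and steroid responsive kinase gene Sgk1 rose from 77.6 ± 14.1 to 138 ± 6.76 CPM. Timp3, an inhibitor of metalloproteinases, fell from 2953 ± 247 to 1932 ± 229 CPM and Loxl1, a matrix crosslinking enzyme gene, from 124 ± 30.5 to 66.4 ± 9.70 CPM. Lpp, which encodes a focal adhesion protein, fell from 1551 ± 186 to 1031 ± 20.2 CPM. Adjusted p-values in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.0360 for Hbegf, Timp3 and Lpp, 0.0481 for Edn1, 0.0225 for Sgk1 and 0.0491 for Loxl1. Like the rest of the 76, each had higher or lower values in all 3 Lmnb1-/- libraries than in any wild type library. The test that selected them favours this, so it is no separate support. With sex as a covariate the calls of Hbegf, Edn1, Sgk1 and Lpp were lost, while their log2 fold changes were 0.63, 0.71, 0.82 and -0.63 against 0.58, 0.79, 0.82 and -0.59 without it. Sgk1 and Lpp passed in male libraries (adjusted p = 0.0293 and 0.0460).

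The second count column, tested in the same way, gave 0 of 1844 genes past the threshold in edgeR's quasi-likelihood test, with 177 at an unadjusted p under 0.05. With sex as a covariate, 4 genes differed between the sexes, Kdm5d, Eif2s3y, Uty and Ddx3y, and none was among the 76. Deviations of wild type and Lmnb1-/- libraries within the number groups correlated at a mean of 0.26. This was the highest of 36 possible labellings, with an exact permutation p of 0.0278 chosen after the correlations were seen, and the next highest gave 0.23.

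Of the tests that follow, those in male libraries and that of contractile cell share were chosen after the results were seen. So were the permutation tests of list scores and the fits with the number groups as a block. The count of 76 genes was reached by 2 of the 35 ways to divide the libraries into 4 and 3, so chance was not excluded, and the highest other division gave 186. That division set wild type replicates 2, 3 and 4 against wild type replicate 1 and the Lmnb1-/- libraries, which points to a structure of the samples beyond genotype. Wild type replicate 1 had 201 CPM of Lmnb1. Chance was likewise not excluded for higher genes (39, reached by 3 of 35, highest other 116), lower genes (37, reached by 2 of 35, highest other 70) and lists called (11, reached by 9 of 35, highest other 16). With the number groups as a block, 40 genes were higher and 53 lower.

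For the lower smooth muscle list, sex imbalance, low depth of wild type replicate 2 and bias of GC content or length were argued against as the whole cause. The median was -0.68 without wild type replicate 2 and -0.69 after a loess trend on GC content and length was removed. In male libraries it was -0.89, with all 21 members below 0. That value rests on wild type replicates 2 and 4, which had the highest scores, 0.53 and 0.49. It leaves out wild type replicate 1, whose score of -0.13 lay nearest the Lmnb1-/- scores. Leaving out wild type replicate 1 alone gave -0.92, so the size of the male-only median cannot be ascribed to sex. Variation between explants shared by these genes stays open, since the list score had an exact permutation p of 0.0571. A smaller share of contractile cells and an effect of genotype within cells cannot be told apart, because the members' log2 fold changes spanned 2.14 and their levels in the other cells of the explant are unknown. For Pdgfrb, DNA of another strain around the targeted allele also cannot be told apart from an effect of genotype, as the exact p of 0.211 for genes within 5 Mb rests on that gene.

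For the higher DNA replication list, the median was 0.57 in male libraries, with 29 of 30 members above 0. This argued against sex imbalance as the whole cause, but it rests on 2 wild type libraries. They include wild type replicate 2, which had the fewest counts and the lowest score. The male libraries also leave out wild type replicate 1, whose score of 0.30 lay among the Lmnb1-/- scores. Leaving out wild type replicate 1 alone gave the same median of 0.57, so the size of the male-only median cannot be ascribed to sex. The median of 0.38 after the loess trend was removed argued against bias of GC content or length. Variation between explants stays open, with an exact permutation p of 0.114 for the list score. The median was 0.19 with the number groups as a block. That block leaves wild type replicates 2 and 3 without an Lmnb1-/- library to be compared with, and their scores of -0.57 and -0.31 were the lowest. The labels give no batch, so what lowered the median cannot be told.

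For the rise of Rassf1, which passed in all 23 alternatives, 3 technical explanations were examined. Rassf1 lies on chromosome 9 and Lmnb1 on chromosome 18, so DNA linked to the targeted allele was excluded. The second count column held 0% of its counts and the log2 fold change with both columns was 1.75, which argues against reads from near-identical copies. The highest log2 fold change among tested genes of the 5 on either side was -0.023, which argues against reads or regulation of those tested genes. Cacna2d2, Zmynd10, Naa80 and Hyal3 were not tested. Zmynd10 lies directly beside Rassf1, so a part of a neighbour was not excluded. That Rassf1 responds to loss of lamin B1 is a hypothesis, found and tested on the same 7 libraries, and unlinked strain differences of the mixed background were not tested.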
